A study of Rattus norvegicus with 10 samples.

How the data were processed

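The data are mRNA sequencing libraries of the left hippocampus from 10 female transgenic rats, 5 untreated and 5 given BT-11 in chow. Groups were taken from the treatment label of each sample. The design text calls the animals male once, while the title, the same text elsewhere and the labels of all 10 samples say female, and female is used here. Transcripts of the Y chromosome, of mitochondria and Xist were not analysed here, so neither a check of sex nor a mitochondrial share was made. RNA was isolated with a column kit, made into strand-specific libraries with a KAPA mRNA kit and sequenced in pairs of 50 bases on an Illumina NovaSeq, per the labels' protocols. Each library is a separate rat, so p-values of single genes and of list levels measure differences against the spread between animals of this cohort. Camera at a preset correlation, described below, instead sets a list's genes against the other genes. Its p-values allow little for members that vary together from animal to animal. Wild-type animals are not analysed here.

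Per the submitters' processing notes, bcl2fastq 2.19.1.403, STAR 2.7.9a, Partek and DESeq2 were used with genome build rn6. The role of each tool, the counting program, its strand setting and the annotation version are not given in the sources used here. The authors deposited 2 tables with the same 14806 transcript rows. The first holds estimated counts (expected counts) per transcript, deposited by the authors without normalization, of which 85.4% are whole within 1e-6. Rows at several loci share a symbol, and near-identical copies can hold equally divided values, so genes with such copies are uncertain. The second deposited table holds a normalized signal, in which every library's counts are multiplied by 1 factor, from 0.822 to 1.15, as a comparison with the first table showed (largest relative deviation 9e-06). Such a factor corrects depth and leaves ribosomal RNA, tissue makeup and length effects in place. Start and end positions are given as deposited, for the span of the transcript row with most counts of a gene. Whether starts count from 0 or 1 could not be settled from the table. 2 symbols had been turned into dates by a spreadsheet and are not named. Of the 13670 symbols, 13147 were found in a RefSeq table of assembly GRCr8, which was used for names only. Older symbols in the gene lists were matched through it where the match was unique, a step added after the tables were seen.

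The design fixed before the data were examined assumed whole counts per gene. Because the values are estimated counts per transcript row, rows were summed by symbol (785 symbols had more than 1 row) and rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 with default settings, which left 12000 and removed 1670. Libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test of BT-11 over untreated with no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 13%. Standard errors were derived from the fold change and the F statistic. Mean and SD values are CPM with TMM scaling. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15 and matplotlib 3.10.9 were used.

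Before the data were examined 44 gene lists were fixed, of immune, glial, neuronal and other cell types, neighbouring tissue, Alzheimer genes, the drug target, metabolism, protein turnover, stress, hormones and the clock, and a sex check. The 39 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. Lists of lymphocytes (4 tested members), hypothalamus and pituitary (3 tested members), red blood cells (1 tested member), mitochondrially encoded genes (0) and the sex check could not be tested. The level of a list in a library was the mean of log2(CPM + 1) over its members, compared by a two-sided exact permutation test of the 252 assignments, whose smallest possible p is 0.00794. These were adjusted over the 8 lists of other cell types and neighbouring tissue. A second adjustment over 25 marker lists was added after seeing the data.

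The genes named were fixed by a rule: up to 12 passing genes in each direction or, where fewer pass, the next by p-value up to 6, said not to pass; up to 4 members with the smallest p-values in each list described; and always Lancl2, App, Mapt, Apoe, Trem2, Gfap, Aif1, Bdnf and Ttr. A few genes that the rule selects are not reported here. They were passed over, and they stay in the counts of genes and in the lists.

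The procedure was tested on simulated data. In 5 runs, counts for the 12000 genes of this comparison were drawn from the measured means, library sizes and dispersions, with 200 genes changed per run. The list of mature oligodendrocytes and myelin was also lowered in each run, and its genes are left out of the counts below. At an adjusted p of 0.05, 15.2% of genes changed by 1.25 times were recovered, 68.4% at 1.5 times, 90% at 2 times and 96% at 3 times, each with the right direction, and 25 of 698 calls were false. The simulation draws genes independently, so it does not test camera against correlated genes. Its recovery also holds only for this number of changed genes, since with fewer the adjustment is stricter.

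The alternatives were other scaling (DESeq2 size factors, upper quartile, library size only), no filter and a filter of 1 CPM in 5 libraries, DESeq2, limma voom with and without sample weights, limma on the deposited normalized values as log2(value + 1), a threshold of 0.10, leaving out each library, the replicate number as a block, 1 surrogate variable, and the level of the choroid plexus or the myelin list as a covariate. For list levels a pseudocount of 0.1 and the median over members were tried. Chosen after seeing the data were the fits without ribosomal RNA genes, on single transcript rows, without the 2 libraries rich in choroid plexus transcripts, with the ribosomal RNA share as a covariate, and DESeq2 with its filtering set for an adjusted p of 0.05. Libraries of a group differed from each other by more than counting noise.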

Results

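Messenger RNA was sequenced from the left hippocampus of 10 female TgF344-AD rats, a transgenic Fischer line that serves as a model of Alzheimer's disease. All animals were 11 months old and had been perfused with buffered saline before the hippocampus was taken. One group of 5 rats ate ordinary chow and is called untreated here. The other group of 5 rats ate chow with BT-11, an orally active small molecule known as a binder of the LANCL2 protein, for 6 months from the age of 5 months. Each library came from 1 animal. The deposited counts summed to between 13721673 and 19700443 per library, and the totals of the groups were not told apart by a two-sided exact permutation test (p = 0.46).

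The comparison asked which hippocampal transcripts differed between BT-11 and untreated transgenic females. Transcripts of myelinating oligodendrocytes were lower in BT-11 libraries, with Ugt8 at 0.767 times its untreated level, but no single gene passed edgeR's test across all genes and the call on the myelin list as a group depended on the test used. Of the 12000 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.8. At an unadjusted p under 0.05 there were 715 genes, 304 higher and 411 lower with BT-11, where 600 would be expected by chance. DESeq2, run on the same counts with default settings, called 8 genes (adjusted p from 0.00517 to 0.037), and 13 with its filtering set for an adjusted p of 0.05, a setting chosen after seeing the data, while limma voom called 0. The settings shared 7 genes, and Tppp3 was called only by the default. Of the 8 genes 1, Cplx2, was higher with BT-11, and 7 were lower, among them Ugt8, Tppp3, Apod, Myo1d, Ndrg1 and Tf.

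Among the lower genes with the smallest p-values were Ugt8, Tppp3, Apod, Zc2hc1c, Ndrg1 and Myo1d, none of which passed edgeR's test (adjusted p = 0.8 for each). Ugt8, the enzyme that makes the myelin lipid galactosylceramide, lies on chromosome 2 at 229644479 to 229718673 in rn6. Levels are given in CPM, counts scaled to library size. Ugt8 measured 102.5 ± 6.73 CPM (SD, n = 5) in untreated rats and 78.6 ± 6.67 CPM (SD, n = 5) with BT-11, a log2 fold change of -0.38 ± 0.0709 (SE). Apod, a lipid carrier of glia (chromosome 11, 72705204 to 72726264), had a log2 fold change of -0.55 ± 0.118 (SE). The log2 fold change was -0.68 ± 0.134 (SE) for Tppp3, a tubulin-binding protein, -0.39 ± 0.0866 (SE) for Ndrg1, a gene expressed in myelinating glia, and -0.56 ± 0.127 (SE) for Myo1d, an unconventional myosin. Zc2hc1c was a low transcript, at 3.06 ± 0.213 CPM in untreated rats and 1.88 ± 0.286 CPM with BT-11 (SD, n = 5 each). Each of these 6 genes lay below the untreated mean in 5 of 5 BT-11 libraries, which adds little, since they were chosen by p-value in these same libraries. Tf, the iron carrier transferrin, was fixed in the list of mature oligodendrocytes and myelin under the symbol Trf. That symbol was not matched to Tf here, so Tf was not tested with the list. The rule for named genes therefore did not select Tf, which was chosen after its values were seen. Its log2 fold change was -0.58 ± 0.133 (SE).

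**Figure D1:**
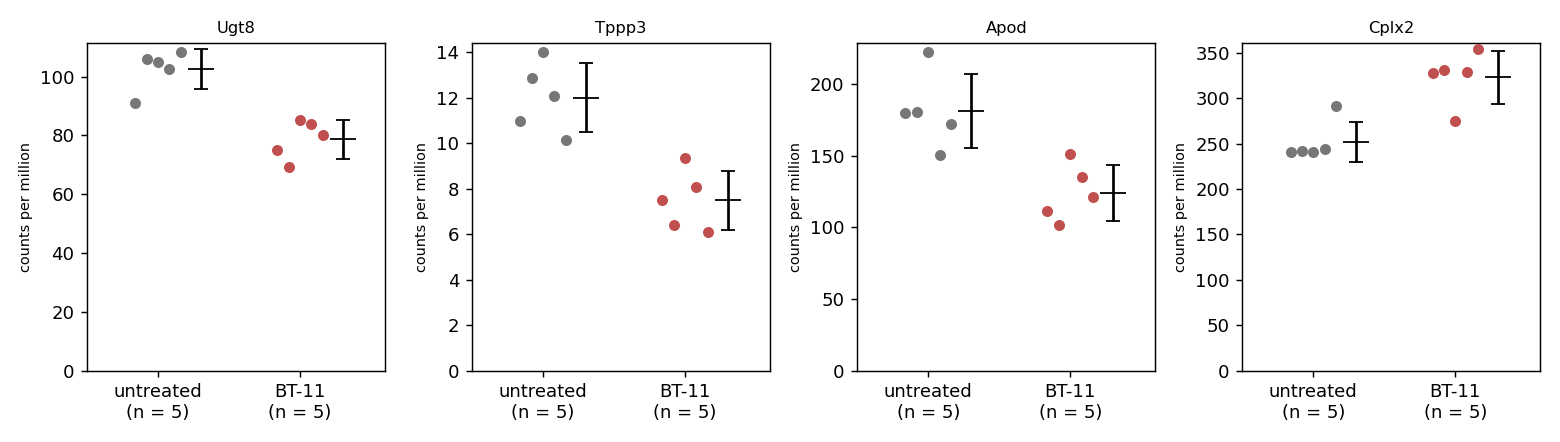
CPM (vertical axes, from 0) of Ugt8, Tppp3, Apod and Cplx2 in each library, with the mean and SD of each group of 5 beside the points. All 5 BT-11 libraries lie below the untreated mean for Ugt8, Tppp3 and Apod and above it for Cplx2. The genes were chosen by p-value in these libraries, and none of them passed edgeR's test across all genes.

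The higher genes with the smallest p-values were Cplx2, Twist1, Qsox2, Nr4a3, Bet1 and Hbb, and none of them passed edgeR's test either (adjusted p = 0.8 for each). Cplx2, a complexin that acts in synaptic vesicle release (chromosome 17, 10757782 to 10766254), measured 251.6 ± 22.1 CPM (SD, n = 5) in untreated rats and 323.2 ± 29.2 CPM (SD, n = 5) with BT-11, a log2 fold change of 0.36 ± 0.0795 (SE). The log2 fold change was 0.60 ± 0.155 (SE) for Nr4a3, an activity-induced nuclear receptor, and 0.63 ± 0.144 (SE) for Twist1, a transcription factor of mesenchymal cells that was low in both groups, at 4.64 and 7.19 CPM. Qsox2, a sulfhydryl oxidase, and Bet1, a protein of vesicle transport from the endoplasmic reticulum, had log2 fold changes of 0.23 ± 0.0566 (SE) and 0.34 ± 0.0931 (SE). The first 5 of these genes lay above the untreated mean in 5 of 5 BT-11 libraries, which again follows largely from their choice by p-value. Hbb, a beta globin of red blood cells, had the largest fold change of the 6, a log2 fold change of 2.95 ± 0.802 (SE). It reached 93.8 CPM in BT-11 library 4, against 2.78 to 19.2 CPM in the other BT-11 libraries and 2.45 to 4.36 CPM in untreated libraries. Without BT-11 library 4 its log2 fold change was 1.56 ± 0.478 (SE). Hbb has near-identical neighbours, so the division of reads among beta globins is uncertain.

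Among 39 gene lists tested, 14 passed an adjusted p of 0.05 with edgeR's camera test at a preset inter-gene correlation of 0.01, 3 higher and 11 lower with BT-11. None of the 14 passed when camera estimated the correlation between members (smallest adjusted p = 0.398 with an estimated correlation) or with fry (smallest adjusted p = 0.484). Without untreated library 3 the number of lists was 7, and without BT-11 library 1 it was 8. It was 6 with limma voom and sample weights, 9 on the deposited normalized values and 8 with 1 surrogate variable as a covariate.

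All 17 tested genes of the mature oligodendrocyte and myelin list were lower with BT-11, with a mean log2 fold change of -0.46 and a range of -0.57 to -0.22 (camera, adjusted p = 1.02e-28; adjusted p = 0.398 with an estimated correlation). Of these members 0 passed when adjusted over all genes and 15 passed when adjusted over the list alone. Besides Ugt8, the members with the smallest p-values include Tspan2 and Mal, membrane proteins of oligodendrocytes. Tspan2 measured 134.6 ± 20.2 CPM (SD, n = 5) in untreated rats and 96.3 ± 16.8 CPM (SD, n = 5) with BT-11, and Mal measured 317.4 ± 48.6 CPM (SD, n = 5) and 220.0 ± 44.0 CPM (SD, n = 5). The mean level of the list was 7.49 ± 0.239 log2(CPM + 1) in untreated rats and 7.04 ± 0.24 log2(CPM + 1) with BT-11 (SD, n = 5 each). This difference of -0.45 had an unadjusted p of 0.0159 in a two-sided exact permutation test. Adjusted over the 25 marker lists tested that way it was 0.398. As 1 list alone could reach no less than 0.198, missing 0.05 there does not count against the list. The unadjusted p, however, makes no allowance for the 25 lists. Levels of the groups overlapped, since BT-11 library 3 stood at 7.29 and untreated library 4 at 7.26. Genes of oligodendrocyte precursors did not pass, with 9 of 11 lower and a mean log2 fold change of -0.12 (camera, adjusted p = 0.0576), but they passed without any one of untreated libraries 1, 4 and 5 or BT-11 libraries 3 and 4 (adjusted p from 0.00793 to 0.0434) and with the replicate number as a block (0.0435), while the mean was -0.05 without untreated library 3. With the myelin level as a covariate they passed as higher (mean 0.16, adjusted p = 0.01). They also passed as lower in settings chosen after seeing the data, without both libraries rich in choroid plexus transcripts (adjusted p = 0.0243) and with the ribosomal RNA share as a covariate (0.0164). These calls are from camera at the preset correlation, and with all libraries the list had an adjusted p of 0.869 with an estimated correlation and 0.814 with fry.

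Neuronal lists moved in both directions. Of 28 genes of the synapse and plasticity list, 27 were higher with BT-11, with a mean log2 fold change of 0.13 (camera, adjusted p = 2.25e-06; adjusted p = 0.45 with an estimated correlation). None of its members passed when adjusted over all genes or when adjusted over the list alone. Those with the smallest p-values include Slc17a7, the vesicular glutamate transporter of excitatory neurons, Camk2a, the kinase of synaptic plasticity, and the neurotrophin Bdnf. Their log2 fold changes were 0.23 ± 0.0819 (SE), 0.25 ± 0.0932 (SE) and 0.34 ± 0.134 (SE), each with an adjusted p of 0.809. With 1 surrogate variable the mean of the list was 0.05 and the call was lost (camera, adjusted p = 0.0628), and with the myelin level as a covariate the mean turned to -0.01 (camera, adjusted p = 0.86). In the list of CA3 and CA2 pyramidal cells, 9 of 13 genes were higher and the mean log2 fold change was 0.14 (camera, adjusted p = 0.0389; adjusted p = 0.869 with an estimated correlation). Its member Cpne4, a copine, had a log2 fold change of 0.53 ± 0.213 (SE), while Coch, an extracellular matrix protein, had one of -0.63 ± 0.193 (SE). In the list of CA1 pyramidal cells, 7 of 9 genes were lower, with a mean log2 fold change of -0.25 (camera, adjusted p = 0.00701; adjusted p = 0.541 with an estimated correlation). Its members Ccn3 and Dcn, both secreted matrix proteins, had log2 fold changes of -0.35 ± 0.122 (SE) and -0.57 ± 0.29 (SE), and Dcn is also a fibroblast gene. The CA1 call was lost with 1 surrogate variable (adjusted p = 0.0582), with the myelin level as a covariate (0.0945) and, in settings chosen after seeing the data, without both libraries rich in choroid plexus transcripts (0.133) and with the ribosomal RNA share as a covariate (0.101). In the interneuron list 13 of 15 genes were lower, with a mean of -0.20 on the log2 scale (camera, adjusted p = 0.000742; adjusted p = 0.541 with an estimated correlation), and 1 passed when adjusted over the list alone against 0 over all genes. That member was the neuropeptide gene Cort, at 2.71 ± 0.753 CPM against 1.49 ± 0.323 CPM (SD, n = 5 each). Pvalb, the calcium-binding parvalbumin of fast-spiking interneurons, had a log2 fold change of -0.24 ± 0.0814 (SE). The CA3 and CA2 mean ranged from 0.08 without untreated library 2 to 0.21 without untreated library 4, and the call was lost without any one of untreated libraries 1, 2 and 3 or BT-11 libraries 1, 2 and 3 (adjusted p from 0.0592 to 0.168). It was also lost with DESeq2 (0.0617), limma voom (0.0644, and 0.148 with sample weights), the deposited normalized values (0.0955), 1 surrogate variable (mean 0.03, adjusted p = 0.677), the myelin level as a covariate (mean 0.02, adjusted p = 0.934) and, chosen after seeing the data, the ribosomal RNA share as a covariate (0.115). The interneuron call was lost without untreated library 4 (adjusted p = 0.0709).

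**Figure D2:**
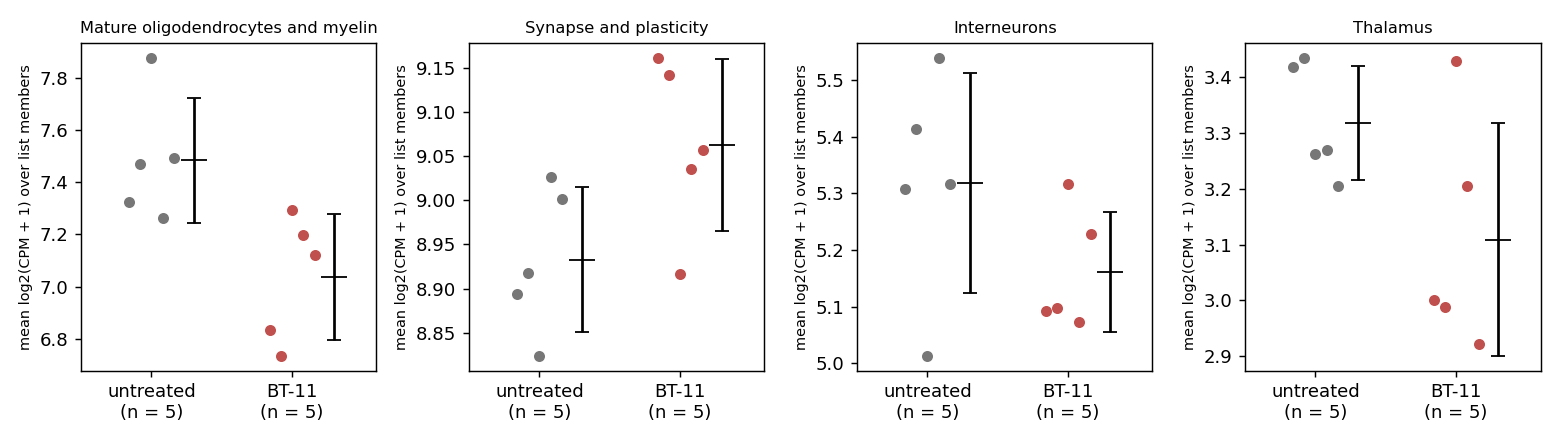
Mean log2(CPM + 1) over the members of 4 gene lists in each library (vertical axes, each with its own range and not starting at 0), with the mean and SD of each group of 5 beside the points. The myelin list averages 7.49 in untreated and 7.04 in BT-11 libraries and the synapse list 8.93 and 9.06, and the groups overlap in all 4 lists.

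A pair of lists of neighbouring brain regions and the list of leptomeninges were also lower. In the thalamus list 9 of 12 genes were lower, with a mean log2 fold change of -0.24 (camera, adjusted p = 0.00701; adjusted p = 0.45 with an estimated correlation), among them Ramp3, a receptor-modifying protein, at -0.64 ± 0.219 (SE), and Calb2, calretinin, at -0.42 ± 0.145 (SE). Calb2 is also a member of the interneuron list. The thalamus call was lost with 1 surrogate variable (adjusted p = 0.0935) and with the myelin level as a covariate (0.312). In the striatum list 10 of 12 genes were lower, with a mean of -0.29 (camera, adjusted p = 0.0389; adjusted p = 0.869 with an estimated correlation). Its members with the smallest p-values went opposite ways, Rarb, a retinoic acid receptor, at 0.29 ± 0.0998 (SE) and Tac1, the precursor of substance P, at -0.75 ± 0.294 (SE) on the log2 scale. In the list of leptomeninges and fibroblasts 14 of 16 genes were lower, with a mean of -0.14 (camera, adjusted p = 0.0472; adjusted p = 0.869 with an estimated correlation), and its member Aebp1, a matrix protein, had a log2 fold change of -0.53 ± 0.155 (SE). By two-sided exact permutation tests of the level per library, 0 of the 8 lists of other cell types and neighbouring tissue passed (smallest adjusted p = 0.571), where 1 list alone could reach no less than 0.0635, so the 0 does not show that these tissues were alike. The striatum mean was -0.19 without untreated library 1, and the call was lost without any one of untreated libraries 1 and 2 or BT-11 libraries 1, 2 and 4 (adjusted p from 0.0633 to 0.18). It was also lost with upper-quartile scaling (0.0509), limma voom (0.0644, and 0.0858 with sample weights), the deposited normalized values (0.0878), 1 surrogate variable (mean -0.08, adjusted p = 0.706) and the myelin level as a covariate (0.257). The leptomeningeal mean ranged from -0.33 without BT-11 library 3 to -0.05 without untreated library 4, and the call was lost without any one of untreated libraries 2, 3 and 4 or BT-11 libraries 1, 2 and 4 (adjusted p from 0.0592 to 0.444). It was also lost with upper-quartile scaling (0.0715), library size only (0.0561), DESeq2 (0.0554), limma voom (0.0832, and 0.34 with sample weights), the deposited normalized values (0.0695), the choroid plexus level as a covariate (0.569) and, chosen after seeing the data, single transcript rows (0.0571). The leptomeningeal mean turned to 0.02 with 1 surrogate variable (adjusted p = 0.823) and to 0.12 with the myelin level as a covariate (adjusted p = 0.257).

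Of the immune lists, 3 were lower by small amounts. In the list of disease-associated microglia, genes known to be induced in microglia around plaques, 13 of 16 were lower, with a mean log2 fold change of -0.18 and a median of -0.09 (camera, adjusted p = 0.0294; adjusted p = 0.869 with an estimated correlation). Its members Cd9, a tetraspanin, and Spp1, osteopontin, had log2 fold changes of -0.32 ± 0.107 (SE) and -1.55 ± 0.583 (SE), and Spp1 stood at 6.35 CPM in untreated library 5 against 0.698 to 1.44 CPM in the other untreated libraries. Cd9 was highest in untreated library 3 and lowest in BT-11 library 2, as was the level of the myelin list, so its difference cannot be assigned to microglia. The 3 members that were higher had log2 fold changes of up to 0.50. Without untreated library 5 the log2 fold change of Spp1 was -0.57 and the mean of the list -0.13, and the list still passed. In the type I interferon list 15 of 21 genes were lower, with a mean of -0.15 (camera, adjusted p = 0.0308; adjusted p = 0.869 with an estimated correlation), and its members Oasl2 and Dhx58, both interferon-induced, had log2 fold changes of -0.48 ± 0.154 (SE) and -0.30 ± 0.152 (SE). In the complement list 11 of 14 genes were lower, with a mean of -0.14 (camera, adjusted p = 0.0389; adjusted p = 0.869 with an estimated correlation). Its members C4a and Serping1, a complement component and the C1 inhibitor, had log2 fold changes of -0.40 ± 0.173 (SE) and -0.42 ± 0.202 (SE), and reads of C4a can be shared with its near-identical copy C4b. The homeostatic microglia list did not pass, with 8 of 14 genes higher and a mean of 0.03 (camera, adjusted p = 0.627), but it passed as higher with 1 surrogate variable (mean 0.13, adjusted p = 0.00437) and with the myelin level as a covariate (mean 0.18, adjusted p = 0.00146). With all libraries it had an adjusted p of 0.885 with an estimated correlation. Its mean fell below 0 without untreated library 4 (-0.00776) or BT-11 library 2 (-0.00244) and was 0.09 without untreated library 3. Without untreated library 3 the adjusted p was 0.235 for disease-associated microglia, 0.283 for interferon and 0.633 for complement, where the mean of complement was -0.02, that of interferon -0.09, and the log2 fold changes of Serping1 and C4a were -0.17 and -0.22. Without BT-11 library 1 the adjusted p was 0.217, 0.153 and 0.201. Calls were also lost without BT-11 library 5 for disease-associated microglia (adjusted p = 0.0513) and interferon (0.109), without untreated library 1 for interferon (0.13) and complement (0.0618), and without BT-11 library 3 for complement (0.0698). With 1 surrogate variable all 3 calls were lost, with means of -0.09 for disease-associated microglia (adjusted p = 0.802), -0.01 for interferon (0.76) and 0.02, in the other direction, for complement (0.76). They were also lost with the myelin level as a covariate, where the means were 0.01 (adjusted p = 0.257), -0.03 (0.743) and 0.07 (0.312), and with limma voom and sample weights (0.203, 0.278 and 0.527). The complement call was lost as well with upper-quartile scaling (0.0509), limma voom (0.0644) and the deposited normalized values (0.082). In settings chosen after seeing the data, calls were lost on single transcript rows for disease-associated microglia (0.367) and with the ribosomal RNA share as a covariate for interferon (0.0505) and complement (0.108).

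Among lists of metabolism and protein synthesis, 48 of 49 genes for cytosolic ribosomal proteins were lower, with a mean log2 fold change of -0.10 (camera, adjusted p = 7.55e-05; adjusted p = 0.869 with an estimated correlation). Rpl10 and Rpl11, proteins of the large subunit, had log2 fold changes of -0.14 ± 0.0777 (SE) and -0.16 ± 0.1 (SE). Nuclear genes of oxidative phosphorylation were lower in 38 of 49 cases, with a mean of -0.04 (camera, adjusted p = 0.0472; adjusted p = 0.869 with an estimated correlation), and the complex I subunits Ndufb10 and Ndufs8 had log2 fold changes of -0.15 ± 0.0552 (SE) and -0.14 ± 0.0928 (SE). Genes of cholesterol synthesis were higher in 17 of 21 cases, with a mean of 0.10 (camera, adjusted p = 0.00456; adjusted p = 0.869 with an estimated correlation), among them Idi1 and Nsdhl, enzymes of the pathway, at 0.21 ± 0.116 (SE) and 0.16 ± 0.0923 (SE). Without untreated library 3 the calls for ribosomal proteins (adjusted p = 0.467), oxidative phosphorylation (0.235) and cholesterol synthesis (0.108) were lost. There the mean of ribosomal proteins was -0.02 and that of cholesterol synthesis 0.06, and the log2 fold changes were -0.09 for Rpl10, -0.09 for Rpl11 and 0.10 for Nsdhl, so the ribosomal protein difference rests largely on this library. Without untreated library 4 the mean of ribosomal proteins was -0.16. The mean of oxidative phosphorylation ranged from -0.07 without BT-11 library 3 to -0.01 without untreated library 1, and Ndufs8 was at -0.08 without BT-11 library 1 and -0.21 without BT-11 library 3. The oxidative phosphorylation call was also lost without untreated library 1 (adjusted p = 0.504) and without any one of BT-11 libraries 1, 2, 4 and 5 (adjusted p from 0.119 to 0.202). With 1 surrogate variable or the myelin level as a covariate, the ribosomal protein list turned higher, with means of 0.06 (camera, adjusted p = 0.00119) and 0.14 (camera, adjusted p = 2.14e-09). Under the same fits oxidative phosphorylation turned to 0.02 (adjusted p = 0.503) and 0.04 (0.184), and cholesterol synthesis lost its call, at 0.03 (0.442) and -0.02 (0.493). Limma voom with sample weights ended the calls for ribosomal proteins (0.0955), oxidative phosphorylation (0.141) and cholesterol synthesis (0.0818). The oxidative phosphorylation call was also lost with library size only (0.0558), no filter (0.0563), the deposited normalized values (0.0616), the choroid plexus level as a covariate (0.164) and, chosen after seeing the data, single transcript rows (0.0571). The remaining lists did not pass (25 lists, adjusted p from 0.0576 to 0.994).

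Lancl2, the reported target of BT-11 (chromosome 4, 88525674 to 88565114), measured 51.1 ± 6.29 CPM in untreated rats and 54.5 ± 3.58 CPM with BT-11 (SD, n = 5 each), a log2 fold change of 0.09 ± 0.086 (SE, adjusted p = 0.846 in edgeR's test), which ranged from 0.02 without untreated library 3 to 0.13 without untreated library 5. The list of LANCL2 and its reported signalling partners did not pass, with 9 of 16 genes lower and a mean log2 fold change of -0.04 (camera, adjusted p = 0.561), but it passed as lower without untreated library 3 (mean -0.09, adjusted p = 0.0464) and with the myelin level as a covariate (mean -0.16, adjusted p = 0.00146), both by camera at the preset correlation. The mean of the list was -0.01 without untreated library 2. With all libraries its adjusted p was 0.869 with an estimated correlation and 0.837 with fry. The list of amyloid and tau genes did not pass either, with 14 of 26 lower and a mean of -0.02 (camera, adjusted p = 0.692). Endogenous and transgenic transcripts of App are not told apart here. App measured 2165 ± 242 CPM against 2245 ± 119 CPM, and Mapt, which encodes tau, measured 856.7 ± 39.3 CPM against 833.2 ± 8.07 CPM (SD, n = 5 each). The log2 fold change was -0.01 ± 0.126 (SE) for the lipid carrier Apoe, -0.08 ± 0.151 (SE) for the microglial receptor Trem2, -0.02 ± 0.125 (SE) for the microglial gene Aif1 and -0.16 ± 0.122 (SE) for the astrocyte filament gene Gfap. For these 6 genes edgeR's adjusted p lay between 0.83 and 0.997. Without untreated library 3 the log2 fold change was -0.03 for Gfap and -0.02 for Mapt, and those of App (-0.02), Apoe (0.07), Trem2 (0.05) and Aif1 (0.06) turned. Apoe and Aif1, both near 0, also turned without untreated library 1 (0.04 and 0.01) or BT-11 library 1 (0.07 and 0.04), Apoe without BT-11 library 2 (0.03) and Aif1 without BT-11 library 4 (0.00127).

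The largest components of variation between libraries were not shown to follow the groups. The first 2 principal components of the 500 most variable genes held 33.7% and 28.9% of the variance and did not separate the groups past the threshold (two-sided exact permutation tests, p = 0.119 and p = 0.841). Both were led by Ttr, the transthyretin gene of the choroid plexus (chromosome 18, 15532964 to 15540178). It measured 1055 CPM in untreated library 4 against 28.0 to 80.8 CPM in the other untreated libraries. In BT-11 library 3 it measured 1196 CPM against 1.63 to 16.8 CPM in the other BT-11 libraries. Outside these 2 libraries, Ttr was lower in every BT-11 library than in any untreated library. Its log2 fold change was -0.02 ± 1.56 (SE), and it became 2.36 without untreated library 4 and -5.29 without BT-11 library 3. The choroid plexus list had 13 of 16 genes lower and a mean log2 fold change of -0.32 (camera, adjusted p = 0.365). Without BT-11 library 3 this mean was -2.49 (camera, adjusted p = 3.1e-06), and without untreated library 4 it was 1.16 (camera, adjusted p = 0.176). The list also passed as lower with the replicate number as a block (mean -0.72, adjusted p = 0.035), with limma voom and sample weights (mean -1.18, adjusted p = 0.0238) and, in settings chosen after seeing the data, with both of these libraries left out (mean -0.65, adjusted p = 0.00325) and with the ribosomal RNA share as a covariate (mean -2.90, adjusted p = 2.91e-07). These calls too are from camera at the preset correlation, while the estimated correlation of its members was 0.837 and the adjusted p with it, over all libraries, 0.885. Ribosomal RNA took 10.7 ± 0.257% of counts in untreated libraries and 9.17 ± 2.1% in BT-11 libraries (SD, n = 5 each; two-sided exact permutation test, p = 0.0714), and BT-11 library 3 stood at 5.63%. With untreated library 4 and BT-11 library 3 both left out, 0 genes passed edgeR's test and 19 lists passed camera, a setting chosen after seeing the data.

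**Figure D3:**
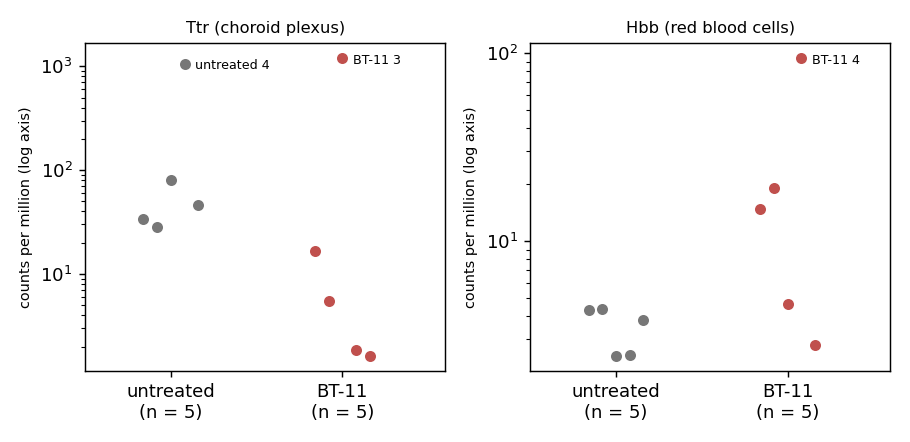
CPM of Ttr and Hbb in each of the 5 untreated and 5 BT-11 libraries, on log axes, with 1 point per library. Ttr stands at 1055 in untreated library 4 and 1196 in BT-11 library 3, and Hbb at 93.8 in BT-11 library 4.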

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

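The tests of hemoglobin were chosen after the results they bear on had been seen. In 140 groups of 5 values (total counts, ribosomal RNA share, list levels and named genes), 11 held 1 library farther from its group than Dixon's 95% limit of 0.71, where chance alone gives about 7.

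Choroid plexus transcripts stood apart in 1 library of each group. The level of the choroid plexus list was 4.99 log2(CPM + 1) in untreated library 4 against 2.12 to 2.63 in the other untreated libraries, and 4.77 in BT-11 library 3 against 1.59 to 2.15 in the other BT-11 libraries. Ttr measured 1055 CPM in untreated library 4 and 1196 CPM in BT-11 library 3. All 16 tested list members were above the mean of the other libraries of the same group in both, and in each of the 2 libraries 15 of the 16 were above every other library of the group. Across these genes, which are not independent replicates, the excess in the 2 libraries ranked alike (Spearman rho = 0.95), so choroid plexus tissue carried along at dissection may account for both. No biological explanation was tested.

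Hbb measured 93.8 CPM in BT-11 library 4, against 2.78 to 19.2 CPM in the other BT-11 libraries, and this library is not the whole of the difference, since without it the log2 fold change was 1.56 ± 0.478 (SE). Blood left after perfusion could raise it, and the other red cell genes followed Hbb by Pearson's r of 0.948 (permutation p = 0.0016, adjusted 0.0032 over 2 relations) but less clearly by rank, with a Spearman rho of 0.527 (permutation p = 0.12, adjusted 0.12). Among the other red cell genes, Hba-a2 held 159.3 counts in BT-11 library 4 against 0.267 to 27.0 in the other libraries. Alas2 held 40 counts there against 0 to 8, while Slc4a1 held 3 against 0 to 3. In that library Hbb was thus not alone among red cell genes. Without the 2 libraries farthest from the median r was 0.676, and with beta globins left out of the sum r was 0.875 and rho 0.6 (adjusted permutation p = 0.0035 and 0.12), while r was 0.329 without the 2 libraries farthest from the median. Remaining blood therefore stays open, since rho fell between the bounds set for it, and so does an effect of BT-11, which was not tested.

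The other libraries that stood apart are given as values. The level of the nuclear oxidative phosphorylation list was 6.71 in BT-11 library 3 against 6.52 to 6.57 in the others of its group. App measured 1752 CPM in untreated library 3 against 2172 to 2342 CPM, and Serping1 30.4 CPM there against 13.8 to 18.5 CPM. Untreated library 5 held Cplx2 at 291 CPM against 240.3 to 244 CPM and Spp1 at 6.35 CPM against 0.698 to 1.44 CPM. Cort measured 2.05 CPM in BT-11 library 4 against 1.24 to 1.45 CPM in the others of its group.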

How the results depend on the processing

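Settings named here as added were chosen after seeing the data; the others were fixed before. The count of 0 genes held in 27 of 29 alternatives, among them each of the 10 fits without 1 library. DESeq2 with default settings called 8 genes (1 higher, 7 lower), and the added DESeq2 setting with filtering for an adjusted p of 0.05 called 13 (1 higher, 12 lower); the cause was not tested. The number of genes at an unadjusted p under 0.05 ranged from 373 (without BT-11 library 2) to 1129 (without untreated library 4) when 1 library was left out. It was 1435 without both libraries rich in choroid plexus transcripts and 1198 with the ribosomal RNA share as a covariate, both added settings. Of 30 alternatives, 23 kept the number of lists within 1.5 times of 14. It was 6 with limma voom and sample weights, 9 on the deposited normalized values and 8 with 1 surrogate variable (the cause was not tested), and 0 with camera at an estimated correlation and 0 with fry, which take the correlation among members into account. Without 1 library it ranged from 7 to 17. The number of lists of other cell types and neighbouring tissue past the exact permutation test was 0 in all 21 alternatives, which says nothing about stability at 0.05, since with 5 against 5 libraries 1 list alone could reach an adjusted p of no less than 0.0635. The mean log2 fold change of the myelin list ranged from -0.52 to -0.34 without 1 library and stayed past camera's threshold in each. Its value of -0.457 had an adjusted p of 0.398 with an estimated correlation and 0.484 with fry.

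Of 30 alternatives, those that kept a list's direction and call were 27 for myelin and for interneurons, 26 for synapse and for thalamus, 24 for CA1, for cholesterol synthesis and for ribosomal proteins, 21 for disease-associated microglia, 20 for interferon, 17 for complement and for striatum, 15 for CA3 and CA2, 14 for oxidative phosphorylation and 12 for leptomeninges. All alternatives except camera with an estimated correlation and fry kept camera's preset correlation, and they shared most or all of the libraries. The alternative with a looser threshold reused the main p-values, so it could lose no call. Much of the agreement was thus built in, and the counts do not measure support for a call. With an estimated correlation and with fry, each of the 14 lists lost its call. Among lists that did not pass, oligodendrocyte precursors passed in 10 alternatives (as higher with the myelin level as a covariate and as lower in the other 9), choroid plexus in 5, homeostatic microglia in 2, LANCL2 partners in 2 and amyloid and tau in 0.

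The labels give no link between same-numbered animals. Correlations of their deviations from the group means were -0.3, -0.06, 0.08, -0.34 and -0.05, which show no pairing but cannot exclude a shared day or litter. With the replicate block 0 genes (0 higher, 0 lower) and 18 lists passed, 571 genes had an unadjusted p under 0.05, and the myelin mean was -0.454.

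Of 1421 log2 fold changes of the 49 named genes under the alternatives, 1380 kept their direction, and 15 genes turned at least once. None of these 15 passed edgeR's test, and the cause of the turns was not tested. With the myelin level as a covariate, which removes that list's difference by construction, the myelin mean was 0.000633. The means then turned for disease-associated microglia (0.0133), complement (0.0745), leptomeninges (0.117), synapse (-0.0114), oxidative phosphorylation (0.044), cholesterol synthesis (-0.0219), ribosomal proteins (0.144), oligodendrocyte precursors (0.155) and amyloid and tau (0.00118). Genes that turned there were Aif1 (0.217), Apoe (0.31), App (-0.144), Bdnf (-0.0523), Gfap (0.0703), Idi1 (-0.0149), Lancl2 (-0.106), Mapt (0.00184), Ndufs8 (0.0679), Nsdhl (-0.0501), Rpl10 (0.0245), Rpl11 (0.104), Serping1 (0.057), Trem2 (0.297) and Ttr (0.12). With 1 surrogate variable the means turned for complement (0.0163), leptomeninges (0.0175), oxidative phosphorylation (0.0222), ribosomal proteins (0.0578) and oligodendrocyte precursors (0.029), as did Aif1 (0.137), Apoe (0.216), App (-0.0505), Gfap (0.00108), Lancl2 (-0.0143), Trem2 (0.133) and Ttr (0.0512). Limma voom with sample weights turned Aif1 (0.0563), Apoe (0.0876) and Trem2 (0.0468), and library size only turned Ttr (0.0534). The added settings turned amyloid and tau (0.013 on transcript rows and 7e-05 without both choroid-rich libraries) and homeostatic microglia (-0.022 without both and -0.00186 with the ribosomal RNA share). Without 1 library the ranges that crossed 0 were -0.106 to 0.0572 for Aif1, -0.0645 to 0.0685 for Apoe, -0.0178 to 0.0783 for App, -0.169 to 0.0458 for Trem2, -5.29 to 2.36 for Ttr, -0.00776 to 0.0922 for homeostatic microglia and -2.49 to 1.16 for the choroid plexus list. In the 20 lists given no value here, 73 of 560 means changed direction and 33 passed the threshold.

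In the simulation, with 200 genes changed per run, 15.2% of changes of 1.25 times were recovered, against 90% of 2 times. Small single-gene changes are thus mostly below what these libraries can detect. Where fewer genes change the adjustment is stricter, so the percentages do not carry over to this comparison. Twist1, at 1.545 times its untreated level, had an adjusted p of 0.8 in edgeR's test.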

Other observations

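The tests of matched random lists and of other groupings for myelin and for the number of genes were chosen after seeing the data, and the other tests below were written before their results were seen. Other groupings of the same libraries show how far these counts can arise by chance. Of the 126 ways to divide the 10 libraries into 5 and 5, 100 were drawn, the real one included. The real grouping gave 0 genes past the threshold, a number that 100 of 100 groupings reach by definition, so it says nothing about chance. The highest other gave 1027. That grouping set untreated libraries 1, 2 and 3 with BT-11 libraries 3 and 4 against the rest, which points to a structure among the libraries that is not the treatment. For genes at an unadjusted p under 0.05, 28 of 100 groupings gave as many as the real 715 (highest other 3568), so chance cannot be excluded. For lists passing camera, 34 of 100 gave as many as the real 14 (highest other 23, median of the others 12), so chance cannot be excluded for the number of lists either.

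For the myelin list, 2 of 100 groupings, the real one among them, moved its mean log2 fold change as far as 0.457 in either direction (highest other 0.467). Few groupings moved the list this far, but it was singled out from 39 lists after its values were seen, so chance is not excluded. Over these lists its adjusted p was 0.398 in camera with an estimated correlation and 0.484 in fry. Transcript length and expression level did not account for it: the list's median of -0.47 lay below all of 10000 random lists matched on both (percentile 0, lowest random median -0.08). A smaller share of oligodendrocytes in the BT-11 pieces and lower expression of the whole program per cell cannot be told apart. With the mean of the other members as a covariate 2 of 17 members had an unadjusted p under 0.05, against 15 before, and the median log2 fold change went from -0.47 to -0.04, but the members vary together (estimated correlation 0.793), so this covariate removes any shift they share, whatever its cause. Both stay open, and an effect of BT-11 on oligodendrocytes stays open as an untested hypothesis.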
